A study of Homo sapiens with 6 samples.

How the data were processed

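RNA sequencing was done on melanocytes derived from the human pluripotent stem cell line H9. Per the labels' protocols, sorted melanoblasts were replated on day 11 of differentiation, infected on day 40 with a lentivirus carrying either Tomato, a red fluorescent protein, or ATAD2, selected with blasticidin for 1 week, and treated with doxycycline for 72 h, which per the series' design text induced BRAF V600E. About 500000 cells were collected per sample. The titles also carry the line label 3xKO, whose meaning is not spelled out in the sources used here. The labels list 6 samples. The deposited table held columns for 5 of them: Tomato replicates 1, 2 and 3 and ATAD2 replicates 2 and 3. The sample labelled ATAD2 replicate 1 was not analysed here.

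Per the submitters' processing notes, the tools were Trim Galore, STAR 2.4, Picard, HTSeq 0.9.1 and DESeq2 with the genome build hg38; the gene annotation, the strand setting of the counting and any filters are not given in the sources used here. The deposited values are a normalized signal, one value per gene and library, in 31071 rows named by gene symbol. Every value was a whole multiple of its column's smallest value above 0, within 0.001 of a read, in 100% of the values of each library, so that read counts divided by one size factor per library were recovered as whole reads. The recovered totals were 45537780, 58264983 and 48708583 reads for Tomato replicates 1, 2 and 3 and 43882918 and 49569900 reads for ATAD2 replicates 2 and 3. The recovered size factors lay between 0.643 in Tomato replicate 1 and 1.13 in Tomato replicate 2. The deposited values of 1 read were 1.56, 0.883, 0.959, 1.13 and 0.928. The median squared difference between libraries over its expected sampling variance, over genes with at least 100 reads, was at least 119 for pairs of the same group and lowest, at 39.6, between Tomato replicate 3 and ATAD2 replicate 3, the pair with the highest correlation (Pearson's r = 0.971), so no library was a repeat of another within sampling noise.

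Symbols were matched to GENCODE release 29 on GRCh38, 19270 by name and 604 through an older symbol, leaving 11197 unmatched; coordinates are 1-based on that build. The members CCN1 and CCN2 of the gene lists were found under their older symbols CYR61 and CTGF. The pluripotency markers NANOG, TDGF1, UTF1 and GDF3 were not analysed here.

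The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(normalized value + 1), ATAD2 minus Tomato, over the 17490 genes with a value of at least 10 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2 scale and understate the change of genes with low values. The filter had been set for 6 libraries and was applied to 5, so a gene read only in the 2 ATAD2 libraries could not enter. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 20 lists, beside camera with an estimated correlation and fry. The lists were pigmentation and melanosome, neural crest and melanoblast, ERK pathway output, DNA replication and S phase, mitosis, MYC targets and ribosome biogenesis, interferon response, p53 pathway targets, dedifferentiated or invasive melanoma, inflammatory secretome, unfolded protein and amino acid stress, cholesterol synthesis, hypoxia and glycolysis, chromatin regulators, fibroblast and matrix markers, neuron markers, Schwann cell and glia markers, pluripotency markers, epithelial and endothelial markers, and mitochondrially encoded genes. Lists, tests and the rule for named genes were set before the data were examined. The rule took ATAD2 and BRAF, the 6 genes past the threshold with the largest rise and the 6 with the largest fall among those with a mean of at least 100 and no overlap between groups, and in each list up to 3 members past the threshold or else the member with the highest mean. The 4 members with the smallest p in each list past the threshold were added after the values were seen. Some genes that the rule takes are not reported here.

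Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of at least 50, quantile and upper-quartile scaling, a robust variance prior, a replicate block, leaving out each library in turn, and, on the recovered reads, the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0. A filter of at least 10 in 2 libraries and a correction of each library for transcript GC content and length (natural splines with 4 degrees of freedom each) were added after seeing the data. The correction covered the 14516 tested genes with a matched transcript, 83.0% of them.

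The tests were checked on simulated data made from these libraries' means, dispersions and depths, 3 against 2. Genes were drawn independently, so shifts shared by many genes were not simulated. The counts of unchanged genes called are therefore not an error rate for the real libraries. The dispersions already held the libraries' own GC trend. Over 17490 genes with 100 changed genes per fold size, limma recovered 8% of 4-fold and 93% of 16-fold changes, with 3 unchanged genes called; with a GC trend added it recovered 4% and 76%, and after the correction, over 14516 genes, 14% and 94%. Reads are not independent molecules, and the 95% intervals given for ratios of reads (exact binomial) cover counting error only.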

Results

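Gene expression was measured in melanocytes differentiated from H9 human pluripotent stem cells after doxycycline-induced expression of BRAF V600E, the activated form of the kinase that drives many melanomas. The cells carried either a Tomato control lentivirus (3 libraries) or a lentivirus with ATAD2 (2 libraries), a bromodomain ATPase that binds chromatin. Libraries held 43882918 to 58264983 recovered reads, and 25285 to 27183 genes had at least 1 read in a library. Mitochondrially encoded genes took 7.06% to 10.9% of the reads.

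The comparison asked which transcripts differed when ATAD2 was delivered to melanocytes with induced BRAF V600E. The ATAD2 transcript itself (chromosome 8, 123319850 to 123416350, GRCh38, protein-coding) overlapped between the groups as labelled. Its values do not separate ATAD2 delivered by the virus from the cells' own, so they are not a measure of delivery alone. Its normalized read count was 955.5, 612.0 and 5303 in the libraries labelled Tomato replicates 1, 2 and 3, and 2232 and 14374 in those labelled ATAD2 replicates 2 and 3. The library labelled Tomato replicate 3 thus held 1.25 more on the log2 scale than the library labelled ATAD2 replicate 2. The means were 2290 ± 2615 (SD, n = 3) and 8303 ± 8586 (SD, n = 2). The log2 fold change was 1.96 ± 1.03 (SE) with limma's adjusted p = 0.597, and an exact two-sided permutation test gave p = 0.3, where the smallest p that 3 against 2 libraries allow is 0.1. Without Tomato replicate 3 the log2 fold change was 2.89 with limma's adjusted p = 0.00538. With replicate number as a block, which the labels do not tie to a shared culture, it was 1.65 (adjusted p = 0.00278; 1.30 and 0.0153 after the GC correction), and ATAD2 was higher with the ATAD2 virus in both pairs of the same number. Tomato replicate 1 is alone in its block and adds nothing to the blocked estimate. The fit without Tomato replicate 1 gave the same 1.65 with limma's adjusted p = 0.955. The block leaves few degrees of freedom, so its p-values lean on the variance shared across genes. All directions below are between libraries as labelled. BRAF (chromosome 7, 140719327 to 140924928), for which the table does not separate the mutant from the normal allele, averaged 2013 ± 910 (SD, n = 3) with Tomato and 3327 ± 1407 (SD, n = 2) with ATAD2, a log2 fold change of 0.79 ± 0.58 (SE; limma, adjusted p = 0.609).

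In the libraries labelled ATAD2, 8 genes were lower and 1 was higher; each averaged 30.5 or less in the group where it was low and 83.3 or more in the other. The filter of at least 10 in 3 libraries keeps out genes read only with ATAD2; with at least 10 in 2 libraries 20 genes were higher and 18 lower, and with no filter 24 and 22. ZEB1 (chromosome 10, 31318495 to 31529814), a transcription factor that represses epithelial genes and promotes mesenchymal states, rose from 7.99 ± 8.85 (SD, n = 3) with Tomato to 897.4 ± 244.0 (SD, n = 2) with ATAD2, a log2 fold change of 7.06 ± 0.80 (SE; limma, adjusted p = 0.0332). On the deposited values, the largest fall was in SLC17A9 (chromosome 20, 62952647 to 62969585), the vesicular nucleotide transporter, from 873.2 ± 106.8 (SD, n = 3) to 2.63 ± 1.09 (SD, n = 2; limma, adjusted p = 0.00239). The Tomato libraries held 2407 of its reads and the ATAD2 libraries 5, a ratio of 335 after scaling (95% interval 143 to 1032). FAM83F (chromosome 22, 39994949 to 40043529) fell from 683.0 ± 86.3 (SD, n = 3) to 2.53 ± 0.37 (SD, n = 2), with 1913 reads against 5 and a ratio of 266 (95% interval 114 to 820; limma, adjusted p = 0.00239). After the GC correction its log2 fold change was -7.66, beyond the -7.48 of SLC17A9.

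The other falls spanned several functions. PRKCB (chromosome 16, 23835946 to 24220611), which encodes protein kinase C beta, a kinase that activates tyrosinase in melanocytes, fell from 1113 ± 61 (SD, n = 3) to 30.5 ± 23.9 (SD, n = 2), a log2 fold change of -5.39. PRICKLE3 (chromosome X, 49175264 to 49186528), a member of the Prickle family of planar polarity proteins, fell from 834.9 ± 355.5 (SD, n = 3) to 15.7 ± 5.1 (SD, n = 2), a log2 fold change of -5.60. CTNND2 (chromosome 5, 10971840 to 11904043), a catenin of adherens junctions, fell from 270.7 ± 44.1 (SD, n = 3) to 4.95 ± 2.19 (SD, n = 2), a log2 fold change of -5.55. RP11-527H14.2, a transcript named by its clone and unmatched in the annotation used here, fell from 592.4 ± 240.5 (SD, n = 3) to 9.54 ± 2.27 (SD, n = 2), a log2 fold change of -5.76. The adjusted p of these 4 genes lay between 0.0196 and 0.0332 (limma). GSTM1 and PCDHB17 were below the mean set for named genes and were added after their values were seen. GSTM1 (chromosome 1, 109687814 to 109709039), a glutathione transferase, had 279 reads with Tomato and 1 with ATAD2, a ratio of 194 (95% interval 34.5 to 7691; limma, adjusted p = 0.0196). PCDHB17 (chromosome 5, 141155996 to 141159061), a transcribed pseudogene of the protocadherin beta cluster, had 244 reads with Tomato and 3 with ATAD2, a ratio of 56.6 (95% interval 19.1 to 276; limma, adjusted p = 0.0332). GSTM1 lies within GSTM2 on the same strand in the annotation, and both it and PCDHB17 have close relatives with which reads can be shared, so their levels are uncertain. ZEB1 overlaps ZEB1-AS1 on the opposite strand, which read 0.88 to 4.67 in the Tomato libraries and 176.8 and 37.1 in the ATAD2 libraries, and the counting strand is not stated.

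**Figure D1:**
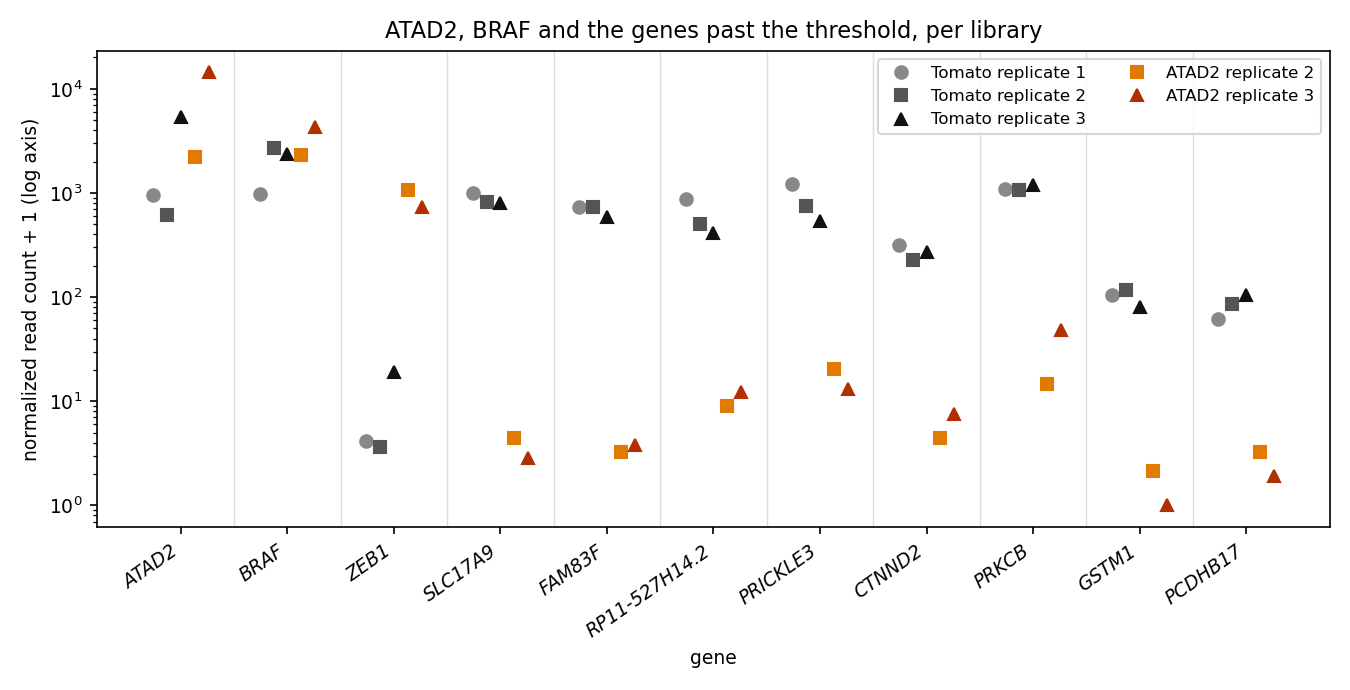
Normalized read count plus 1 (log axis) of ATAD2, BRAF and the 9 genes past the threshold, one point per library (grey and black, the 3 Tomato libraries; orange and red, the 2 ATAD2 libraries). ATAD2 and BRAF overlap between the groups, while SLC17A9, for example, lies at 802.3 or above in every Tomato library and at 3.40 or below in both ATAD2 libraries.

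The number of genes past the threshold depended on single libraries, on the genes tested and on the correction for GC content. Of 17490 genes, 1435 had an unadjusted p under 0.05. No gene passed without ATAD2 replicate 2 or without Tomato replicate 1, while 995 were higher and 427 lower without Tomato replicate 3, 25 higher and 9 lower without Tomato replicate 2, and 70 higher and 33 lower without ATAD2 replicate 3. On the 14516 genes with a matched transcript, limma called 5 genes without a correction. After the correction for transcript GC content and length, 45 of them were higher and 56 lower, and 8 of the 8 genes past the threshold over all genes that had a transcript were among these. The quasi-likelihood test of edgeR on the recovered reads called 0 higher and 2 lower, and DESeq2 called 375 and 167.

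Pigment genes were lower in both ATAD2 libraries. Of 24 tested members of the pigmentation and melanosome list, 22 were lower and 2 higher, with a mean log2 fold change of -1.21, and the list fell by camera with the preset correlation (adjusted p = 7.07e-09), though not with an estimated correlation (adjusted p = 0.432) or by fry (adjusted p = 0.140, and 0.0625 by its mixed test). No member passed over all genes; 12 were lower adjusted over the list alone. The mean over the list was 14.45, 14.08 and 13.83 in the Tomato libraries and 12.81 and 13.01 in the ATAD2 libraries. The 2 higher members were DCT and MYO5A, with log2 fold changes of 0.30 and 0.72. MITF overlapped between the groups, at 5248, 8248 and 15121 with Tomato and 4717 and 7027 with ATAD2 (limma, adjusted p = 0.638). GPR143, a receptor of the melanosome membrane mutated in ocular albinism, averaged 9994 ± 4896 (SD, n = 3) with Tomato and 778.4 ± 200 (SD, n = 2) with ATAD2, with an adjusted p of 0.0535 (limma). TYRP1, a melanosomal enzyme, averaged 400922 ± 76539 (SD, n = 3) and 132715 ± 11828 (SD, n = 2). RAB38, which directs traffic to melanosomes, averaged 10643 ± 2414 (SD, n = 3) and 3117 ± 1030 (SD, n = 2), and OCA2, a melanosomal transporter, 31190 ± 9246 (SD, n = 3) and 10235 ± 763 (SD, n = 2). PMEL, the fibril protein of melanosomes and the list's most abundant member, read 1068710, 333707 and 278628 with Tomato and 127066 and 118524 with ATAD2; it overlaps CDK2, another member, on the opposite strand.

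The neural crest and melanoblast list did not move in one direction: 13 of its 28 tested members were higher and 15 lower (camera, adjusted p = 0.95), with a mean of 0.14 and a median of -0.12. The list passed fry's mixed test, which takes no account of direction (adjusted p = 0.00406), but not its directional test (adjusted p = 0.864); no member passed over all genes, and 1 was higher and 0 lower adjusted over the list alone. SOX10, the crest regulator that maintains the melanocyte lineage, averaged 48020 ± 29827 (SD, n = 3) with Tomato and 17837 ± 2355 (SD, n = 2) with ATAD2 (limma, adjusted p = 0.597).

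Genes of dedifferentiated or invasive melanoma were higher with ATAD2. Of 23 tested members, 20 were higher, with a mean log2 fold change of 1.94 (camera, adjusted p = 4.28e-10; adjusted p = 0.432 with an estimated correlation). ZEB1 alone passed over all genes, and 9 members were higher adjusted over the list alone; fry's directional test gave an adjusted p of 0.140 and its mixed test 0.0277. F2RL1, a protease-activated receptor, averaged 233.7 ± 55.6 (SD, n = 3) with Tomato and 2469 ± 108 (SD, n = 2) with ATAD2. EGFR, the epidermal growth factor receptor, averaged 62.7 ± 26.1 (SD, n = 3) and 1159 ± 913 (SD, n = 2). WNT5A, a Wnt ligand of invasive melanoma cells, read 128.5 to 252.1 with Tomato and 59023 and 2298 in ATAD2 replicates 2 and 3. The mean over the list was 10.13, 10.44 and 10.07 with Tomato and 12.70 and 11.61 with ATAD2, and without ATAD2 replicate 2 the mean log2 fold change was 1.16.

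Fibroblast and matrix markers were higher mainly in the library labelled ATAD2 replicate 2. The list mean was 8.39, 8.99 and 7.84 with Tomato, 13.13 in ATAD2 replicate 2 and 9.56 in ATAD2 replicate 3, and 18 of 20 members were higher, with a mean log2 fold change of 2.94 (camera, adjusted p = 4.28e-10; adjusted p = 0.555 with an estimated correlation). None passed over all genes and 12 were higher adjusted over the list alone. POSTN, the matrix protein periostin, read 63.8 to 228.1 with Tomato and 18537 and 3832 with ATAD2. COL3A1, a fibrillar collagen, read 94.9 to 494.9 with Tomato and 60819 and 1782 with ATAD2, and COL1A2, the list's most abundant member, 682.5 to 2698 and then 200175 and 5818. PDGFRA, a receptor of mesenchymal cells, read 13461 in ATAD2 replicate 2 and 158.7 in ATAD2 replicate 3. TAGLN and THY1, by contrast, read 171.1 and 546.3 in ATAD2 replicate 2, within the range of the Tomato libraries. Without ATAD2 replicate 2 the list mean fell to a log2 fold change of 1.15.

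The inflammatory secretome list was likewise highest in ATAD2 replicate 2. Its mean was 8.08, 9.49 and 8.28 with Tomato and 11.82 and 9.01 with ATAD2, and 18 of 19 tested members were higher, with a mean log2 fold change of 1.80 (camera, adjusted p = 1.31e-06; adjusted p = 0.640 with an estimated correlation). No member passed over all genes or adjusted over the list alone. CXCL8, the neutrophil chemokine interleukin 8, read 239.7 to 2577 with Tomato and 58365 and 4009 with ATAD2. PTGS2, the inducible cyclooxygenase, averaged 6544 ± 4992 (SD, n = 3) and 27032 ± 20858 (SD, n = 2). The list's call was lost without ATAD2 replicate 2 (mean log2 fold change 0.39, adjusted p = 0.213).

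Proliferation genes differed between the 2 ATAD2 libraries. DNA replication and S phase genes were lower on average, 26 of 32 members, with a mean log2 fold change of -0.61 (camera, adjusted p = 0.00119; adjusted p = 0.743 with an estimated correlation), and none passed singly over all genes or adjusted over the list alone. The list mean was 11.60, 11.22 and 11.35 with Tomato, 10.09 in ATAD2 replicate 2 and 11.46 in ATAD2 replicate 3, and without ATAD2 replicate 2 the mean log2 fold change was 0.07. MCM7, a subunit of the replicative helicase, read 4924 in ATAD2 replicate 2 and 13402 in ATAD2 replicate 3, against 11743 to 34899 with Tomato. The mitosis list was not called, with 14 members higher and 16 lower and a mean log2 fold change of -0.15 (camera, adjusted p = 0.302). Its mean was 10.31 in ATAD2 replicate 2 and 12.04 in ATAD2 replicate 3, below and above all 3 Tomato libraries. Without ATAD2 replicate 3 the list's mean log2 fold change was -1.01, and without ATAD2 replicate 2 it was 0.72. Each of these fits held a lone ATAD2 library, so the spread between ATAD2 libraries was not measured. FOXM1, a transcription factor of mitotic genes, averaged 20542 ± 11344 (SD, n = 3) and 6680 ± 5691 (SD, n = 2; limma, adjusted p = 0.529).

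Cholesterol synthesis, interferon and unfolded protein genes were lower by the preset test. Of 20 cholesterol synthesis genes, 16 were lower, with a mean log2 fold change of -0.77 (camera, adjusted p = 0.00119; adjusted p = 0.555 with an estimated correlation), and the call was lost without ATAD2 replicate 2 (-0.55, adjusted p = 0.0506). FDPS, which makes farnesyl pyrophosphate, averaged 5769 ± 2023 (SD, n = 3) with Tomato and 2825 ± 557 (SD, n = 2) with ATAD2. Of 27 interferon response genes, 21 were lower, with a mean log2 fold change of -0.79 (camera, adjusted p = 0.0019; adjusted p = 0.743 with an estimated correlation). The interferon list stood at 11.87 in Tomato replicate 2 and between 9.70 and 10.06 in the other 4 libraries, and its call was lost without Tomato replicate 2 (mean log2 fold change -0.16, adjusted p = 0.390). MX1, an antiviral GTPase, read 21753 in Tomato replicate 2 and 1443 to 5383 elsewhere, and IFI6 averaged 27764 ± 17524 (SD, n = 3) and 7690 ± 824 (SD, n = 2). Of 20 unfolded protein and amino acid stress genes, 15 were lower, with a mean log2 fold change of -0.49 (camera, adjusted p = 0.0394; adjusted p = 0.692 with an estimated correlation). The call was lost after the GC correction (-0.39, adjusted p = 0.113; -0.34, adjusted p = 0.0745 with the replicate block added), without ATAD2 replicate 2 (-0.24, adjusted p = 0.404), with quantile normalization (-0.39, adjusted p = 0.108), with the replicate block (-0.35, adjusted p = 0.0583) and with DESeq2 (-0.45, adjusted p = 0.0563). PHGDH and PSAT1, enzymes of serine synthesis, averaged 27690 ± 16192 and 18937 ± 5810 (SD, n = 3) with Tomato and 10223 ± 5021 and 8939 ± 4309 (SD, n = 2) with ATAD2, while HSPA5, the endoplasmic reticulum chaperone BiP, averaged 36418 ± 9379 (SD, n = 3) and 46123 ± 4669 (SD, n = 2). No member of these 3 lists passed over all genes or adjusted over the list alone.

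Markers of neurons were higher by the preset test. Of 11 tested neuron markers, 9 were higher, with a mean log2 fold change of 0.90 (camera, adjusted p = 0.0451; adjusted p = 0.555 with an estimated correlation), and 1 was higher adjusted over the list alone. GAP43, a growth cone protein, averaged 54.7 ± 27.1 (SD, n = 3) with Tomato and 853.1 ± 840.3 (SD, n = 2) with ATAD2, while NEFL, a neurofilament and the list's most abundant member, read 4767 and 21477 in the ATAD2 libraries against 9152 to 23430 with Tomato. The call was lost without Tomato replicate 1 (mean log2 fold change 0.66, adjusted p = 0.143), without ATAD2 replicate 3 (0.77, adjusted p = 0.266), with a pseudocount of 8 (0.82, adjusted p = 0.0581), with a filter of at least 50 (0.97, adjusted p = 0.0570) and with quantile normalization (0.83, adjusted p = 0.0527).

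Of the remaining lists, ERK pathway output was not called on the deposited values, with 14 of 22 members higher and a mean log2 fold change of 0.23 (camera, adjusted p = 0.216), and was called higher after the GC correction (0.33, adjusted p = 0.0187; adjusted p = 0.695 with an estimated correlation). PHLDA1, an ERK-induced gene, read 5729 to 10333 with Tomato and 47856 and 18365 with ATAD2 (limma, adjusted p = 0.355). In hypoxia and glycolysis, 14 of 20 members were lower (adjusted p = 0.134), in chromatin regulators 21 of 32 were higher, and all 13 mitochondrially encoded genes were lower (adjusted p = 0.188 for each). The adjusted p was 0.684 for each of Schwann cell and glia markers, epithelial and endothelial markers and p53 pathway targets, 0.714 for pluripotency markers and 0.717 for MYC targets and ribosome biogenesis (camera with the preset correlation). Hypoxia and glycolysis was called lower without Tomato replicate 2 (mean log2 fold change -0.52; camera, adjusted p = 0.0284). Its mean log2 fold change was -0.72 without ATAD2 replicate 2. Mitochondrially encoded genes had a mean log2 fold change of -0.65 without ATAD2 replicate 2. MYC targets had mean log2 fold changes of -0.52 without ATAD2 replicate 3 and 0.47 without ATAD2 replicate 2. The fits without ATAD2 replicate 2 or 3 each held a lone ATAD2 library. Chromatin regulators were called higher with quantile normalization (0.35; camera, adjusted p = 0.0468). In these lists no member passed over all genes; adjusted over the list alone, 1 glial marker was higher, and 1 epithelial or endothelial and 1 pluripotency marker were lower. The mean of the Schwann cell and glia list was 0.31 and its median -0.09. The 5 tested pluripotency markers as a list passed fry's mixed test (adjusted p = 0.00406) but not its directional test (adjusted p = 0.734). After the GC correction they did not pass fry's mixed test either (adjusted p = 0.145). ENO1, a glycolytic enzyme, averaged 226931 ± 104060 (SD, n = 3) with Tomato and 135118 ± 2545 (SD, n = 2) with ATAD2, and BRD2, a bromodomain protein, 15807 ± 2057 (SD, n = 3) and 13238 ± 661 (SD, n = 2). MT-CO1 averaged 1026650 ± 405033 (SD, n = 3) and 788198 ± 322452 (SD, n = 2). KDR, a receptor for vascular endothelial growth factor, averaged 3164 ± 1673 (SD, n = 3) and 2876 ± 2119 (SD, n = 2), and TNFRSF10B, a death receptor, 13094 ± 3018 (SD, n = 3) and 12167 ± 2161 (SD, n = 2). LIN28B averaged 906.5 ± 513.0 (SD, n = 3) and 2214 ± 2000 (SD, n = 2), and NPM1, a nucleolar chaperone, 31527 ± 18960 (SD, n = 3) and 49606 ± 27676 (SD, n = 2).

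**Figure D2:**
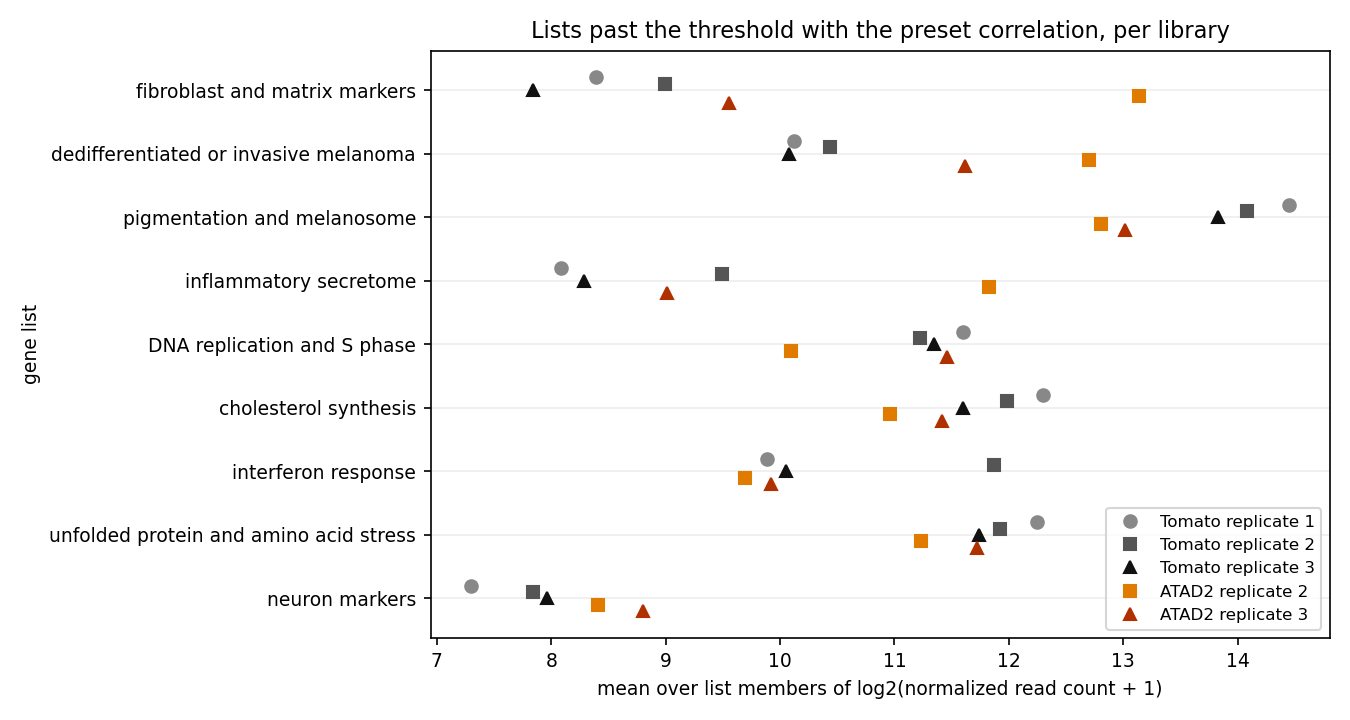
Mean over list members of log2(normalized read count + 1) for the 9 lists past the threshold with the preset correlation, one point per library (grey and black, the 3 Tomato libraries; orange and red, the 2 ATAD2 libraries). The pigment list is lower in both ATAD2 libraries (12.81 and 13.01) than in any Tomato library (13.83 at the lowest), whereas the matrix list stands at 13.13 in ATAD2 replicate 2 and 9.56 in ATAD2 replicate 3.

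The libraries differed in how their values followed transcript GC content, across and within groups. GC content accounted for 55.9% of the variance of gene deviations in Tomato replicate 1, 15.1% in Tomato replicate 2, 39.3% in Tomato replicate 3, 3.06% in ATAD2 replicate 2 and 30.6% in ATAD2 replicate 3. In the eighth of genes with the lowest GC content (median 37.4%), Tomato replicate 1 lay at -1.11 and Tomato replicate 3 and ATAD2 replicate 3 at 0.55 and 0.56 on the log2 scale. In the eighth with the highest (median 63.4%), these libraries lay at 1.17, -0.64 and -0.45. ATAD2 has a transcript GC content at the low end, and its corrected values were 1925, 775.6 and 3780 in the Tomato libraries and 1780 and 9932 in the ATAD2 libraries, a log2 fold change of 1.24 (limma, adjusted p = 0.497). BRAF moved from a log2 fold change of 0.79 to -0.04.

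**Figure D3:**
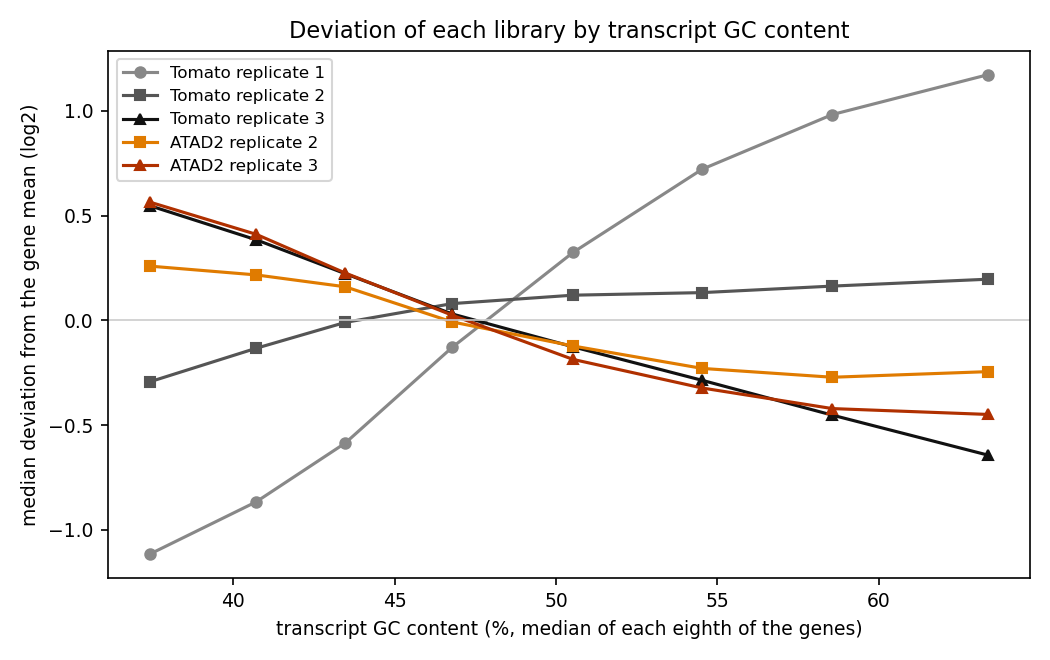
Median deviation of genes from their mean over libraries (log2) against transcript GC content (%, median of each eighth of the 14516 genes with a matched transcript), one line per library (grey and black, Tomato; orange and red, ATAD2). Tomato replicate 1 climbs from -1.11 to 1.17, while Tomato replicate 3 and ATAD2 replicate 3 descend from 0.55 and 0.56 to -0.64 and -0.45.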

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

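The filter of at least 10 in 2 libraries and the GC and length correction were chosen after seeing the data; the other alternatives were set before. The genes higher and lower with ATAD2, 1 and 8 on the deposited values, became 5 and 11 with a pseudocount of 8, 24 and 22 with no filter, 0 and 8 with a filter of at least 50, 3 and 13 with quantile normalization, 0 and 2 at an adjusted p under 0.01, 0 and 2 with edgeR, 375 and 167 with DESeq2, 20 and 18 with at least 10 in 2 libraries, and 45 and 56 with the GC and length correction. A pseudocount of 0.5, upper-quartile scaling, the robust prior and a log2 fold of at least 1 left 1 and 8. Leaving out each library in turn gave 0 to 995 higher and 0 to 427 lower, and a log2 fold change of ATAD2 from 0.61 to 3.30, past the threshold without Tomato replicate 3. In the fits without a Tomato library, most genes low with ATAD2 fell under the filter by its construction (3 or 4 of the 9 were tested). ATAD2 replicate 1 had no column, so every fit was without it. A lone ATAD2 library was assumed to vary like the Tomato libraries.

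The 2 replicate numbers shared by both groups do not mark a shared culture in the labels. Tomato replicate 1 has no partner and adds nothing to the fold changes of a blocked fit, which keeps few degrees of freedom. With the replicate block, 531 genes were higher and 331 lower, and ATAD2's log2 fold change was 1.65 (limma, adjusted p = 0.00278); with the GC and length correction and the replicate block, 407, 311 and 1.30 (adjusted p = 0.0153). The difference of replicate 2 minus 3 correlated across genes between the groups at 0.358, and at 0.365 after correction; genes are not independent replicates.

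The number of lists called was 9, 8 to 10 when a library was left out and 0 with the correlation estimated per list. With libraries left out, the mean log2 fold change of the S phase list ran from -1.29 to 0.0678. That of the mitosis list ran from -1.01 to 0.722. Both lists reversed by camera without ATAD2 replicate 2, a fit with a lone ATAD2 library. Over all alternatives, 325 list values kept camera's direction and side of the threshold, 23 fell short of it, 7 passed it, 2 reversed (above) and 19, not called, had the other direction by camera, which the mean fold change did not always share. The pigment, matrix and dedifferentiated lists lost camera's call only with the estimated correlation. Every other alternative kept the preset correlation of 0.01, whereas the estimates for these lists were 0.131, 0.777 and 0.133. Keeping the call in those alternatives therefore does not test that setting. None of these lists passed fry's directional test on the deposited values (adjusted p = 0.140, 0.461 and 0.140). Only the dedifferentiated list passed fry's mixed test on those values (adjusted p = 0.0625, 0.193 and 0.0277). After the GC correction the pigment and dedifferentiated lists passed fry's mixed test (adjusted p = 0.0263 for each), and the matrix list did not (0.154). Fry's directional test was again not passed by these lists (adjusted p = 0.0950, 0.400 and 0.0950). For named genes, 445 values stayed, 19 fell short, 21 passed and 16, not called, changed sign. Of the losses, 8 were without ATAD2 replicate 2, at log2 fold changes of -8.25 to -4.52, and 7 with edgeR, at -7.20 to -5.13 and 6.79 for ZEB1. BRAF changed sign with the GC correction (-0.04). The causes were not tested. With 3 against 2 libraries, simulated 4-fold changes were mostly missed (8% recovered), so genes short of the threshold are not shown to be unchanged.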

Other observations

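Apart from the values of limma's main fit, the tests in this part were chosen after the results were seen. Of 20 tested HOX genes, 7 were lower in both libraries labelled ATAD2 than in every Tomato library and 0 were higher in both. The share of all tested genes so separated is not given here, so these counts lack a background. The HOXA and HOXD groups, of 3 tested genes each, fall below the 5 tested members required of the fixed lists. HOXD8, HOXD9 and HOXD13, homeobox genes of 1 cluster that specify posterior identity, averaged 414.6 ± 45.2, 189.4 ± 31.0 and 259.8 ± 48.4 (SD, n = 3) with Tomato and 91.0 ± 40.6, 17.2 ± 24.3 and 48.1 ± 34.4 (SD, n = 2) with ATAD2. The 3 tested HOXD genes had a mean log2 fold change of -3.28 (camera with the preset correlation, p = 3.12e-05, adjusted over 5 groups p = 0.000156; unadjusted p = 0.0895 with an estimated correlation; unadjusted p = 0.00216 after the GC correction). HOXA10 averaged 88.1 ± 29.5 (SD, n = 3) and 12.9 ± 11.9 (SD, n = 2), and HOXA11 256.9 ± 42.3 (SD, n = 3) and 67.8 ± 59.0 (SD, n = 2), while HOXA13 overlapped (1.56 to 22.05 with Tomato, 5.67 and 13.92 with ATAD2). The 3 HOXA genes (camera with the preset correlation, unadjusted p = 0.0121) and all 20 HOX genes (unadjusted p = 8.37e-05) had mean log2 fold changes of -1.67 and -1.11 and did not pass after the GC correction (-1.53, unadjusted p = 0.0589 and -0.75, unadjusted p = 0.0864), nor with an estimated correlation (unadjusted p = 0.202 and 0.247). By limma's camera, the HOXC genes had a mean log2 fold change of -0.34 (adjusted p = 0.175) and the HOXB genes -0.84 (adjusted p = 0.175). No HOX gene passed limma's threshold singly, before or after the GC correction.

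The genes of this paragraph were picked singly after their values were seen, and no shared function was tested. NLRP2 averaged 1011 ± 52 (SD, n = 3) with Tomato and 23.0 ± 27.8 (SD, n = 2) with ATAD2, and FAM50B 411.8 ± 101.1 (SD, n = 3) and 22.6 ± 12.7 (SD, n = 2); both had limma's adjusted p = 0.0535 and passed after the GC correction (0.0325 and 0.0282). PEG10 averaged 3020 ± 750 (SD, n = 3) and 16426 ± 278 (SD, n = 2; adjusted p = 0.0855, and 0.0215 after correction). The neighbours NDN and MAGEL2 of chromosome 15 averaged 2881 ± 731 and 173.1 ± 46.6 (SD, n = 3) with Tomato and 895.9 ± 71.3 and 38.2 ± 7.6 (SD, n = 2) with ATAD2, without passing. After the correction, the 45 higher genes included POSTN (43.0-fold) and EGFR (13.4-fold), and the 56 lower genes included GPR143 (8.73-fold) and BEST1 (4.66-fold). Some genes read in the ATAD2 libraries and nearly absent from every Tomato library, such as ACKR3 and SFRP2, did not enter the main test. Others that were low with Tomato, such as ZEB1 and MXRA5, entered it because a Tomato library also reached the minimum value of the filter. ACKR3, a chemokine receptor, read 1026 and 209.8 with ATAD2 and at most 3.11 with Tomato, and SFRP2, a secreted Wnt modulator, read 754.8 and 156.9 with ATAD2 and had 2 reads in all with Tomato.

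The ATAD2 transcript was higher in the library labelled Tomato replicate 3 than in the one labelled ATAD2 replicate 2, by 1.25 on the log2 scale. The trend with GC content and length amounted to 0.16 at ATAD2 (95% bootstrap interval 0.12 to 0.20) and so covers only part of the difference. The S phase list was lower in ATAD2 replicate 2 than in Tomato replicate 3 by 1.39 ± 0.09 (SE over 32 genes), more than the 1.09 of ATAD2 after correction, but a smaller share of replicating cells stays open as a candidate explanation, since ATAD2 minus the list was -0.57, -1.55 and 0.42 in Tomato replicates 1, 2 and 3 and 0.73 and 1.73 in ATAD2 replicates 2 and 3, a spread among the Tomato libraries beyond the difference in question. An exchange of these 2 labels, or a wrong label on Tomato replicate 3 alone, stays open, since the values go both ways: of 117 genes in which Tomato replicates 1 and 2 differed from ATAD2 replicate 3 by at least 3 (log2), ATAD2 replicate 2 was nearer to ATAD2 replicate 3 in 60.7%, Tomato replicate 3 nearer to Tomato in 44.4%, both with their labels in 42.7% and both against them in 37.6%, which became 90.7%, 95.3%, 88.4% and 2.33% of 43 genes after the GC correction, while at a gap of at least 1 both were with their labels in 13.5% and against them in 25.8% (28.1% and 27.6% after correction) and at a gap of at least 2 in 15.5% and 34.2% (64.6% and 13.1%). Tomato replicate 3 correlated best with ATAD2 replicate 3 on the deposited values (r = 0.971) and with Tomato replicate 2 after correction (r = 0.972, against 0.965 with ATAD2 replicate 3), and each of the 2 regroupings gave 0 genes at 5 or less on one side and at 50 or more on the other, against 8 for the labels; poor expression of the transgene in ATAD2 replicate 2 was not tested.

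The genes that were at 5 or less in 1 group and at 50 or more in the other, 4 lower and 4 higher with ATAD2, did not occur in the other splits of the 5 libraries: the real split gave 8 and the highest of the others 0 (1 of 10 splits), but 10 splits are too few for a share under 0.05. After the GC trend was removed, 8 of the 8 genes past the threshold with a transcript passed. They had been picked from these data for large changes, so this outcome was nearly fixed. Among them were the 4 lower genes, SLC17A9, FAM83F, GSTM1 and PCDHB17. Their corrected log2 fold changes were -7.48, -7.66, -5.68 and -4.81, which argues against the GC trend for these 4. The 4 higher genes were not in that test. A lost chromosome segment spanning the 500 kb around each of the 4 lower genes is argued against. After the GC correction, the mean log2 fold change of the genes there had a 95% interval above -1 at each. A value of -1 is the loss of 1 of 2 copies. The interval lay below 0 at GSTM1, the lowest, -0.45 (-0.75 to -0.15, 20 genes). It also did at FAM83F, -0.27 (-0.54 to -0.00072, 9 genes), and it spanned 0 at PCDHB17 and SLC17A9. These intervals take neighbouring genes as independent. A loss confined to the gene itself, or to it and a few neighbours, was not tested. Cultures of different origin, such as separate differentiations or subclones of the line, are a candidate explanation. It cannot be told apart from an effect of ATAD2, because the labels give no origin apart from the virus. That all 8 genes follow the virus was fixed by how they were picked.

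The pigment list was lower in both ATAD2 libraries, and the matrix list was higher in both but unevenly. Matrix-rich cells taking up part of the cultures could lower pigment genes, but after correction the matrix list was 11.1-fold higher in ATAD2 replicate 2 than in ATAD2 replicate 3, whereas the pigment list differed by only -0.28 (95% interval over genes -0.58 to 0.02), less than the fall of 1.10 in ATAD2 replicate 3. These values argue against such cells as the whole cause of the lower pigment genes, but they compare 1 library with 1 other. The interval takes genes as independent and does not measure the spread between libraries. Matrix-rich cells stay open for the matrix genes of ATAD2 replicate 2, although the cultures came from sorted melanoblasts replated on day 11. Removing the GC and length trend left the pigment list at -1.24 against -1.21 before, which argues against that trend. A loss of melanocyte identity under ATAD2 is a hypothesis that stays open beside a difference between cultures; no test here decides it, which would take both viruses in parallel cultures of 1 differentiation.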
